A study of Homo sapiens with 6 samples.

How the data were processed

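Messenger RNA was measured in 6 libraries of EndoC-βH1 cells, 3 control and 3 cytokine-exposed. Per the labels' protocols, 75000 cells per well adhered for 24 h in medium with 11 mM glucose, and the cocktail, with doses in ng/ml, held IL-17 at 100, IFN-γ at 50, TNF-α at 10 and IL-1β at 5. Per the labels' protocols, cells were kept with or without the cocktail for 24 h, poly(A) RNA was selected, and directional libraries had inserts of 200 to 500 bases with a median near 300 bases. The labels describe the control libraries as taken before exposure, while the extraction protocol describes cells without cytokines over the same 24 h, so a part of the difference that belongs to time in culture cannot be excluded from these sources.

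Per the submitters' processing notes, the reads went through bcl2fastq, FastQC 0.10.1, STAR 2.5.2b, StringTie, Cuffdiff 2.2.1 and DESeq with genome build hg38. The read counter, the strand setting and the annotation are not given in the sources used here. The signal in the authors' deposited count tables is the mean over 6 libraries of read counts divided by size factors, per the file headers. The log2 values in the authors' deposited tables are fold changes of cytokine over control and, in the count tables, their SE, per the file headers. The score in the authors' deposited count tables equals the log2 fold change divided by its SE, within 9.66e-13, and Cuffdiff's own test statistic is the score in the deposited FPKM tables. The p-values and adjusted p-values or q-values are those of the authors' DESeq and Cuffdiff tests as deposited, per the file headers. The FPKM values are group values of the authors' Cuffdiff run as deposited, per the file headers, and its smallest p-value was 5e-05.

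The count tables held 55868 loci with and 5827 loci without a gene name. Of these 61695 loci, 17081 had no read, 14408 had reads but no adjusted p, and 30206 had an adjusted p, the smallest of them with a mean of 1.34016 normalized counts. A Benjamini-Hochberg adjustment over both tables together differed from the deposited adjusted p by at most 1.53e-15, with a tolerance of 1e-09. Loci without a gene name held 1.339% of the normalized counts. The loci are bundles of assembled transcripts, and 2890 named loci held more than 1 symbol. Among tested loci, 965 held at least 2 protein-coding genes and 10.5% of the counts. A value of such a locus belongs to all its genes. The FPKM gene table held 63707 loci, of which 21865 were tested, 41605 were too low to test, 228 had too much data for the tool and 9 failed. Each of the 228 had a group listed at 0 FPKM, so these were left out of comparisons with that table. The isoform table held 274669 transcripts, 95649 of them tested.

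These tables hold only the comparison and no values per library, so the planned tests on values per sample were not run. The authors' deposited adjusted p at a threshold of 0.05 was used as theirs, which the design written before the data were examined gave for this case. That design also fixed the gene lists, the rule for named genes and all alternatives except 3. Means per group were worked out from the deposited mean and fold change. Size factors were recovered from loci taken to hold 1 read in 1 library, because their SE was the largest. Such a locus has a mean of 1 over 6 times the size factor, and the factors cannot be tied to replicate numbers. In simulated counts over 61695 loci the recovery returned all 6 factors. There the single-read loci and their group were marked in advance, so whether the largest deposited SE marks them was not tested. Where the control mean lay under 1 normalized count per library, a floor of 3 reads over the control group was used, and a bound is given only for genes whose fitted control mean was that of a group without reads and whose Cuffdiff control level was listed at 0 FPKM.

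Lists were tested with the camera test for a given statistic in limma 3.58.1 (R 4.3.3) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 20 lists and 25725 named loci as background. In 50 simulated data sets over these 25725 loci, normal scores of the ranks of the statistic were shuffled and 5 lists were shifted by 1 SD. There, 93.6% of shifted and 0.549% of unshifted lists were called. Shuffling makes genes independent, so these rates do not cover genes that vary together or the extreme values of the deposited statistic. Loci were matched to lists by symbol, then through older symbols. The match through RefSeq synonyms, which added ERO1B and NECTIN2, was made after the list results had been seen and moved the beta cell identity list from past the threshold to not past it. The earlier match is given as an alternative. A set of 6 marker lists of other cells was summarised without a test. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Coordinates of named genes came from GENCODE release 44, and 14194 gene identifiers in the tables were identical to it.

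Named genes followed a fixed rule, and the results of some genes it names are not reported here. It took the 12 named genes that rose and the 12 that fell most among those past the threshold with at least 50 normalized counts and the same direction in Cuffdiff, the 5 most abundant past the threshold, and 20 genes fixed by name. From each list it took the 3 largest changes past the threshold and the most abundant member. For isoforms it took 5 per direction with at least 1 FPKM in both groups, and 5 genes with opposite isoforms. Members named because a count was 5 or fewer, CRELD1, VHL, XBP1, PSMB8, TAP1 and UBD, and the members of other cell types and of families in the closing section, were chosen after their values were seen. Loci were called undercounted where a locus of at least 10 FPKM had under 1 in 20 of the reads expected of a transcript of 1 kb.

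Alternatives were the Cuffdiff table, other thresholds, a minimum fold of 2, minimum counts of 10 and 100, named loci alone and another adjustment. For lists they were the Cuffdiff statistic, loci of at least 50 counts, a rank version, a correlation of 0.05 and lists without shared genes. Added after the results were seen were re-centring, loci of a single protein-coding gene with undercounted loci left out, and lists without RefSeq synonyms.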

Results

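Messenger RNA of EndoC-βH1 cells, a human pancreatic beta cell line, was measured in 6 libraries. Of these, 3 came from control cells and 3 from cells exposed for 24 h to a cocktail of IL-1β, TNF-α, IFN-γ and IL-17, cytokines present in inflamed islets. The question was which transcripts of a beta cell line change under acute exposure to these cytokines. The authors' deposited tables hold 1 comparison, cytokine against control, with a log2 fold change and the standard error (SE) of their fit for each locus. The mean depth was 40881975 normalized counts per library in the authors' deposited tables. Size factors were recovered from loci taken to hold a single read in the deposited table. They were 0.917, 1.06 and 1.16 in the control libraries and 0.915, 0.923 and 1.08 in the cytokine libraries. At loci of at least 1000 counts, the deposited SE implied a spread between libraries of a group beyond counting noise. Its median coefficient of variation was 2.70%, with quartiles of 2.19% and 3.32%. The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Coordinates are those of genome build hg38 (GENCODE release 44).

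Among the 12 named genes of at least 50 counts with the largest rises were CXCL9, CXCL10, BST2 and 3 guanylate-binding proteins. The ranking used the deposited fold change, a fitted value where control had almost no reads, so genes ranked that way need not exceed others by their bounds. CXCL10 (chromosome 4, 76021118 to 76023497), a chemokine that attracts T cells, went from a mean of 5.09 to 245439 normalized counts in the authors' deposited table, a log2 fold change of 15.56 ± 0.36 (SE). Its neighbour CXCL9 (chromosome 4, 76001275 to 76007509) went from 0.343 to 34076 normalized counts in the deposited table. That control mean lies under the floor of 3 reads over the control group, so the size of this fold and its order beside CXCL10 are uncertain. The guanylate-binding proteins GBP5, GBP1 and GBP4, GTPases of the defence against intracellular pathogens, rose by 13.40 ± 0.65, 12.90 ± 0.28 and 12.50 ± 0.72 on the log2 scale in the authors' deposited table. BST2 (chromosome 19, 17402939 to 17405630), which tethers budding virus to the cell, was listed at 0 FPKM in control and was at least 5123-fold higher with cytokines in the authors' deposited tables, against a floor of 3 reads over the control group. Against the same floor, the deposited tables put IFI44 at least 584-fold and SERPINB7 at least 453-fold higher. OR2I1P (chromosome 6, 29550407 to 29557773) was at least 8844-fold higher in the deposited tables, but it overlaps UBD (29555515 to 29559732) on the opposite strand. The strand used in counting is not given in the sources used here, so the value of OR2I1P is uncertain. RARRES3 and the ISG15-conjugating enzyme UBE2L6 rose by 11.15 ± 0.35 and 11.04 ± 0.48 in the authors' deposited table, from 5.41 and 2.86 counts in control. XAF1, counted as a single locus with FBXO39, went from 0.343 to 2712 normalized counts in the deposited table.

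The largest falls among named genes of at least 50 counts were smaller in size than the largest rises. GRIN2A (chromosome 16, 9753404 to 10182928), a subunit of the NMDA-type glutamate receptor, fell by 3.84 ± 0.30 (log2 ± SE), from 167 to 11.7 normalized counts, in the authors' deposited table, and stood at -2.26 in the deposited Cuffdiff table, where GLI2 stood at -3.68. GLI2, a transcription factor of Hedgehog signalling, fell by 3.51 ± 0.37 in the deposited table, and FGFR2, a fibroblast growth factor receptor, stood at -3.19 ± 0.27. CCDC3, PEAR1, FAM101B and SCARA3 had deposited log2 fold changes of -3.18, -3.16, -2.97 and -2.76, all past the threshold. The sodium channel gene SCN7A and the nicotinic acetylcholine receptor gene CHRNA4 both stood at -2.67 in the authors' deposited table, and NPR1, a receptor for natriuretic peptides, at -2.62 ± 0.12. The long noncoding RNAs LINC01497 and C15orf59-AS1 stood at -3.41 and -2.88 in the deposited table. Of the 5 most abundant loci past the threshold, CHGA and CXCL10 rose, while GNAS, counted with an antisense RNA, EEF1A1 and ACTG1 fell by 0.13, 0.47 and 0.09 in the authors' deposited table. The fall of ACTG1 was not past the threshold in the deposited Cuffdiff table (q = 0.383).

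At an adjusted p threshold of 0.05 of the authors' DESeq test, 11388 of 30206 loci differed between the groups (37.7%). Of these, 5442 were higher and 5946 lower in cytokine-exposed cells in the authors' deposited tables. The majority depended on centring, since 6197 were higher and 5142 lower after log2 fold changes were re-centred on the median of abundant loci. A change of at least 2-fold was reached by 1972 of the higher and 988 of the lower loci in the deposited tables. Loci of a single protein-coding gene gave 3547 higher and 4519 lower of 13030. The direction varied with abundance in the authors' deposited tables. Among loci under 10 counts, 409 were higher and 79 lower, and among loci of 10 to 100 counts 1024 were higher and 597 lower. From 1000 to 10000 counts, 2343 were higher and 3173 lower, and over 10000 counts 243 were higher and 390 lower. The authors' deposited Cuffdiff table called 7798 of 21865 genes at q under 0.05, 3887 higher and 3911 lower. Of 20201 loci tested by both tools, 6953 were called by both, 6947 of them in the same direction and 6 in opposite directions. A further 3820 loci were called in the count table only and 646 in the Cuffdiff table only. Both tools ran on the same 6 libraries, so their shared calls are no independent check.

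**Figure D1:**
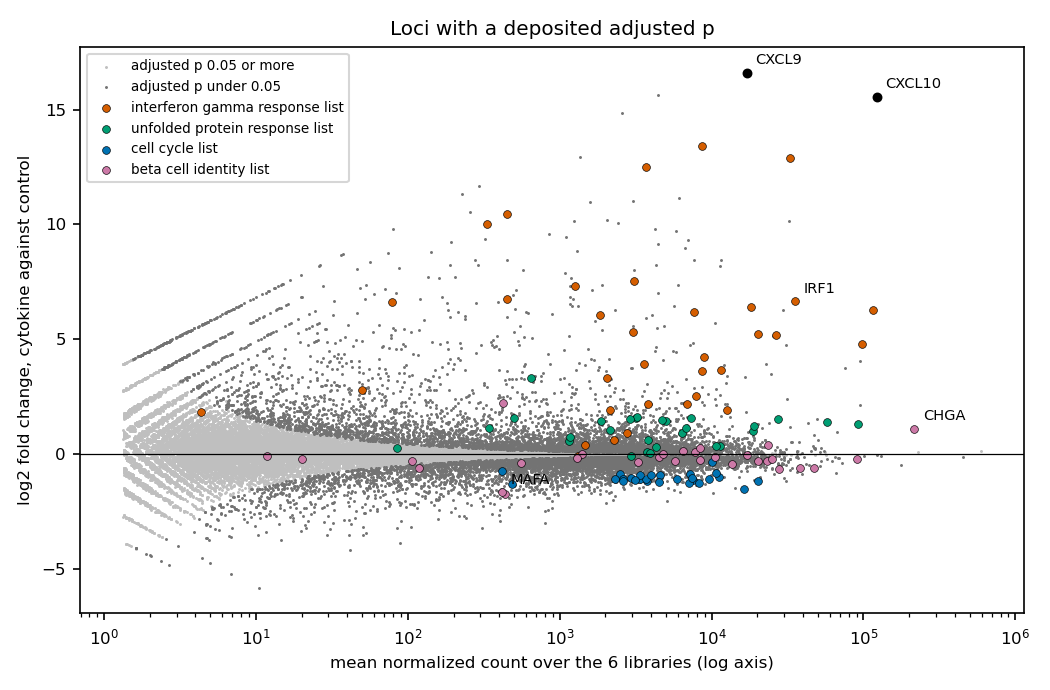
Log2 fold change of cytokine against control (vertical axis) by mean normalized count over the 6 libraries (horizontal log axis) for the 30206 loci with a deposited adjusted p, dark grey where it is under 0.05; coloured points are members of 4 gene lists. CXCL9 and CXCL10 stand at 16.60 and 15.56, the first a fitted value with a control mean under 1 normalized count, so their order is uncertain. The cell cycle list lies under the line of no change.

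The list tests set each fixed list of genes against all other named loci with limma's camera test on the authors' deposited statistic, at a preset correlation of 0.01 between genes, adjusted over 20 lists. An estimated correlation needs values per library, which were not used here. With a preset correlation of 0.05 in its place, 14 lists kept a call against 15 with 0.01, and the call that was lost is given beside its list. List counts hold both adjusted over all genes and adjusted over the list alone, except where both are given.

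Genes downstream of interferon rose almost without exception. Of 34 genes of the IFN-γ response, 32 rose and 0 fell in the authors' deposited table, with a median log2 fold change of 5.00 (list test, adjusted p = 8.09e-311). IRF1 (chromosome 5, 132440440 to 132508719), a transcription factor induced by interferon, rose by 6.67 ± 0.03, from 692 to 70366 normalized counts, in the authors' deposited table. The tryptophan tRNA ligase WARS rose by 6.29 ± 0.02 to 229500 normalized counts in the deposited table, the highest level of the list. The 2 genes not past the threshold were IFNGR1 (-0.08 ± 0.05) and IFI16 (1.84 ± 0.97) in the deposited table. All 32 tested antiviral interferon-stimulated genes rose in the authors' deposited table, with a median of 4.58 (list test, adjusted p = 7.34e-113). OAS3, a sensor of double-stranded RNA and the most abundant of them, rose by 3.35 ± 0.03 in the deposited table.

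Transcripts of antigen presentation genes rose for both MHC classes. All 18 tested loci of MHC class I presentation rose in the authors' deposited table, with a median of 3.58, or 3.13 with a locus of near-zero control at its floor (list test, adjusted p = 9.30e-236). B2M (chromosome 15, 44711358 to 44718851), the invariant class I chain, rose by 4.08 ± 0.02 to 178600 normalized counts in the deposited table. HLA-B and HLA-C, counted as a single locus, stood at 10.16 ± 0.11 in the authors' deposited table. Reads of these near-identical genes can be split between copies, so their separate levels are uncertain. PSMB8 and TAP1 shared a locus with few counted reads. The immunoproteasome subunit PSMB9, counted with an antisense RNA, and the class I transactivator NLRC5 rose by 8.98 ± 0.16 and 8.21 ± 0.09 in the deposited table. Of 12 class II loci, 10 rose in the authors' deposited table, with a median of 6.23, or 4.61 with 6 loci of near-zero control at their floor (list test, adjusted p = 2.66e-51). CD74, the invariant chain, rose by 4.77 ± 0.03 to 59492 normalized counts and the protease CTSS, which trims it, by 9.32 ± 0.18 in the authors' deposited table. HLA-DRA was listed at 0 FPKM in control and reached 72.7 normalized counts, at least 72.7-fold higher, and HLA-DQB1 at least 21.8-fold, in the deposited tables. HLA-DRB1 (3.17 ± 1.68) and HLA-DOA (3.30 ± 1.68) did not pass the threshold in the deposited table.

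NF-κB target genes and secreted mediators rose as well. Of 27 NF-κB targets, 26 rose and 1, TNFAIP8, fell in the authors' deposited table, with a median of 1.92 (list test, adjusted p = 9.25e-33). The NF-κB inhibitor NFKBIA rose by 2.66 ± 0.03 and the mitochondrial superoxide dismutase SOD2 by 2.19 ± 0.03 in the deposited table. IL32, TNFRSF9 and the adhesion molecule ICAM1, counted with ICAM4, rose by 10.20 ± 0.44, 7.74 ± 0.60 and 9.79 ± 0.27 in the authors' deposited table. Among 31 tested chemokines and cytokines, 24 rose and 0 fell in the deposited table, with a median of 3.91, or 3.76 with 6 loci at their floor (list test, adjusted p = 7.31e-23). The neutrophil chemokine CXCL8 rose by 9.44 ± 0.46, from 3.18 to 2205 normalized counts, in the authors' deposited table. Of 17 genes of the IL-17 response, 15 rose in the deposited table, with a median of 3.91, or 3.63 at the floor (list test, adjusted p = 1.70e-13), and MMP3 (-1.01 ± 0.76) and IL36G (0.39 ± 1.342) were not past the threshold. Without genes shared with other lists, 7 loci of this list remained (list test, adjusted p = 0.00527). The cytokines were given together, so no part of the rise can be assigned to IL-17. CCL20 was listed at 0 FPKM in control and at least 51.6-fold higher with cytokines in the deposited tables, and CXCL5 went from 0.343 to 148 normalized counts. The deposited Cuffdiff table gave CXCL9, XAF1, GBP4 and CXCL5 higher levels with cytokines but q of 0.381, 0.369, 0.223 and 0.281.

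The complement list held 10 higher and 2 lower loci of 13 in the authors' deposited table, with a median of 2.204 (list test, adjusted p = 1.58e-10). C3, the central complement protein, rose by 8.23 ± 0.73 from 1.27 to 381 normalized counts in the deposited table, and C2 and CFB, counted as a single locus, stood at 8.22 ± 0.15. SERPING1, the C1 inhibitor, went from 0.344 to 27.0 normalized counts, and the most abundant member CD46 stood at 0.11 ± 0.02 in the authors' deposited table. C5 and CD59 fell, and CFI (0.59 ± 1.16) was not past the threshold in the deposited table. The call of this list was lost with the Cuffdiff statistic (adjusted p = 0.0918) and over loci of a single protein-coding gene (adjusted p = 0.0958). Of 10 receptors and antagonists of the cocktail's own cytokines, 7 rose, or 8 adjusted over the list alone, and 1, the decoy receptor IL1R2, fell in the authors' deposited table, with a median of 0.39 (list test, adjusted p = 0.150). TNFRSF1B and TNFRSF1A, the receptors for TNF, rose by 4.19 ± 0.49 and 1.01 ± 0.10 in the deposited table. IL17RC, in a locus with CRELD1 and VHL, stood at 0.38 ± 0.02, and IL1RN, listed at 0 FPKM in control, was at least 3.66-fold higher in the deposited tables. IFNGR1 (-0.08 ± 0.05) and IL1R1 (0.30 ± 0.15) were not past the threshold over all genes.

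Chaperones and other genes of the unfolded protein response rose together. Of 28 tested, 24 rose and 0 fell in the authors' deposited table, or 25 adjusted over the list alone, with a median of 1.16 (list test, adjusted p = 1.00e-42). HSPA5 (chromosome 9, 125234853 to 125241382), the main chaperone of the endoplasmic reticulum, rose by 1.42 ± 0.02 to 84009 normalized counts in the deposited table, and HSP90B1 by 1.338 ± 0.02 to 132053. HERPUD1, CRELD2 and the stress-induced transcription factors DDIT3 and ATF3 rose by 1.60 ± 0.03, 1.64 ± 0.04, 1.60 ± 0.09 and 3.31 ± 0.10 in the authors' deposited table. Those not past the threshold over all genes were ATF6 (-0.07 ± 0.04), SESN2 (0.04 ± 0.03), TRIB3 (0.08 ± 0.04) and DDIT4 (0.26 ± 0.20). XBP1 had 0 counted reads and was listed at 113 FPKM in control and 213 FPKM with cytokines in the authors' deposited Cuffdiff table (q = 0.000232).

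Of 29 genes of apoptosis and other cell death, 20 rose and 6 fell in the authors' deposited table, with a median of 1.01, or 1.00 with 2 loci at their floor (list test, adjusted p = 4.75e-11). CASP10 and the necroptosis effector MLKL rose by 6.21 ± 0.36 and 6.17 ± 0.21, and CASP1 went from 0.343 to 27.3 normalized counts in the deposited table. MCL1, an antiapoptotic member of the BCL2 family and the most abundant of the list, rose by 1.09 ± 0.02 in the authors' deposited table. BAX (-0.05 ± 0.03), BAD (0.13 ± 0.10) and TNFRSF10A (1.12 ± 1.56) were not past the threshold in the deposited table. Among 25 genes of oxidative and nitrosative stress, 9 rose and 6 fell in the authors' deposited table, with a median of 0.07 (list test, adjusted p = 5.59e-04), and a rank version of the test gave adjusted p = 0.346. The metal-binding proteins MT2A and MT1X rose by 5.59 ± 0.07 and 1.74 ± 0.05 and TXNIP fell by 0.29 ± 0.04 in the deposited table. NOS2, the inducible nitric oxide synthase, shared a locus with LYRM9 at 0.78 ± 0.15, and the deposited Cuffdiff table put that locus at 0.18 (q = 0.225). Of 11 immune checkpoint ligands and enzymes, 8 rose and 3, VTCN1, PVR and CD276, fell in the authors' deposited table, with a median of 1.46 (list test, adjusted p = 4.74e-36). CD274 (chromosome 9, 5450503 to 5470566), which encodes PD-L1, rose by 5.95 ± 0.08 from 118 to 7305 normalized counts in the deposited table. HLA-E, a ligand of inhibitory receptors on natural killer cells, rose by 3.77 ± 0.02, and IDO1, a tryptophan-degrading enzyme, went from 0.636 to 666 normalized counts in the authors' deposited table.

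All 27 genes of the cell cycle list fell in the authors' deposited table, with a median of -1.06 (list test, adjusted p = 8.74e-41). RRM2, a subunit of the enzyme that makes deoxynucleotides, fell by 1.51 ± 0.03, from 24057 to 8457 normalized counts, in the deposited table. CCNE2, the replication helicase subunit MCM4 and the topoisomerase TOP2A stood at -1.28 ± 0.09, -1.25 ± 0.03 and -1.16 ± 0.03 in the authors' deposited table. Of 19 glycolysis loci, 10 fell and 2, PFKP and PKM, rose in the deposited table, with a median of -0.15 (list test, adjusted p = 0.150). The glucose transporter SLC2A1, ALDOC and GAPDH stood at -0.90 ± 0.05, -0.56 ± 0.17 and -0.23 ± 0.02, and the phosphofructokinase PFKP at 1.79 ± 0.04, in the authors' deposited table. The fall of ALDOC was not past the threshold in the deposited Cuffdiff table (q = 0.685). Of 20 genes of cholesterol synthesis and uptake, 15 rose and 4, among them SREBF2 and DHCR7, fell in the authors' deposited table, with a median of 0.27 (list test, adjusted p = 5.59e-04). The Cuffdiff statistic gave this list an adjusted p of 0.0530. The sterol transporter STARD4 rose by 1.59 ± 0.03 and the sterol sensor INSIG1 by 0.58 ± 0.02 in the deposited table. MVK (-0.04 ± 0.04) was not past the threshold.

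**Figure D2:**
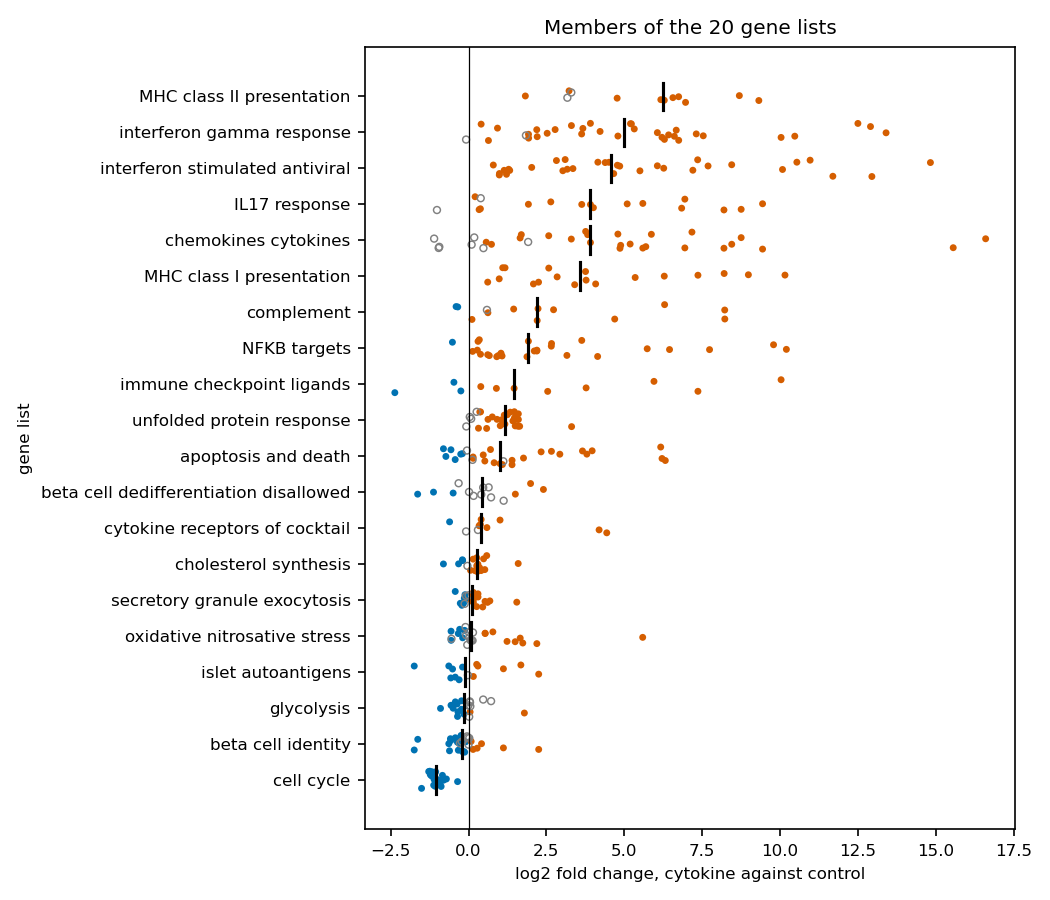
Log2 fold change of cytokine against control (horizontal axis) for the tested members of the 20 gene lists (vertical axis), orange where a locus rose, blue where it fell and open grey where it did not pass the threshold; black bars are list medians. Medians run from -1.06 for the cell cycle to 6.23 for MHC class II presentation.

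Beta cell genes moved in both directions. Of 30 beta cell identity genes, 18 fell and 6 rose in the authors' deposited table, with a median of -0.22, and the list as a whole did not pass the list test (adjusted p = 0.0824). MAFA (chromosome 8, 143419182 to 143430732), a transcription factor of the insulin gene, fell by 1.63 ± 0.10, from 634 to 205 normalized counts, in the deposited table. G6PC2 (chromosome 2, 168901291 to 168910000), the islet glucose-6-phosphatase, fell by 1.74 ± 0.10 in the authors' deposited table. The locus of INS (chromosome 11, 2159779 to 2161221) stood at -0.57 ± 0.05 in the deposited table, but it was counted together with IGF2, H19 and ASCL2, so the level of insulin transcripts alone is uncertain. PDX1 (-0.02 ± 0.02, adjusted p = 0.562), NKX6-1 (-0.00 ± 0.03, adjusted p = 0.978) and the glucose transporter SLC2A2 (-0.28 ± 0.18, adjusted p = 0.257) were not past the threshold of the authors' DESeq test. CHGA, the granule protein chromogranin A, rose by 1.12 ± 0.02 to 296413 normalized counts in the deposited table. IAPP, the islet amyloid polypeptide, shared a locus with SLCO1B1, SLCO1B3 and other genes, and that locus rose by 2.25 ± 0.10 in the deposited table. The list test depended on 1 gene: before the older symbol of ERO1B (0.42 ± 0.02 in the deposited table) was matched, 29 genes gave adjusted p = 0.0334, and that match was made after this result had been seen. Across the other settings the adjusted p ran from 0.00332 in a rank version to 0.219 at a correlation of 0.05.

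**Figure D3:**
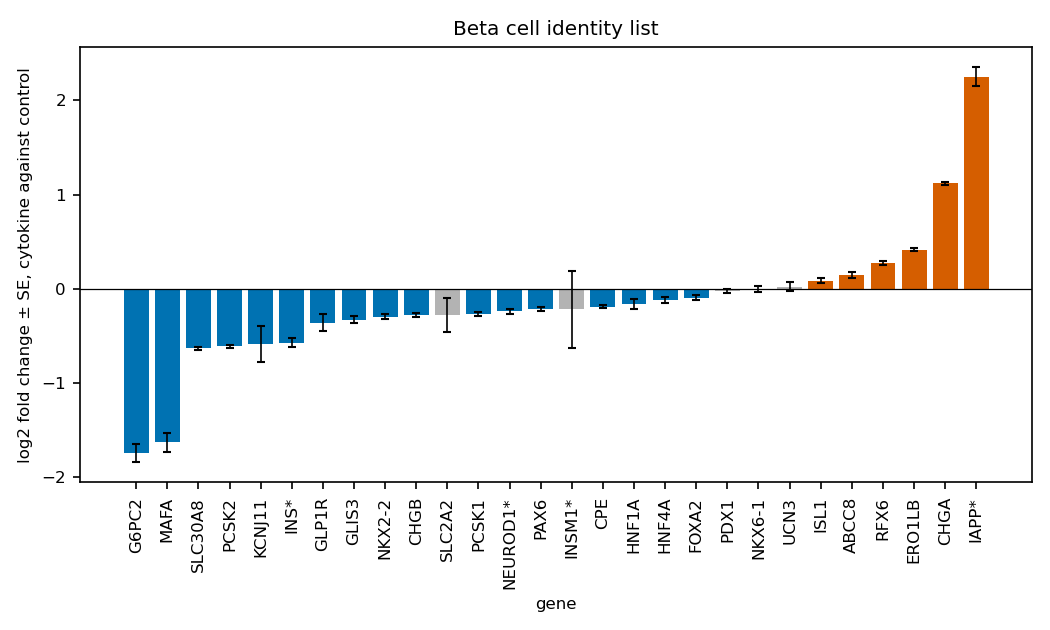
Deposited log2 fold change of cytokine against control with the authors' SE (vertical axis) for 28 of the 30 beta cell identity genes (horizontal axis), blue where a gene fell, orange where it rose and grey where it did not pass the threshold; an asterisk marks a locus shared with other genes or with few counted reads. Bars run from -1.74 for G6PC2 to 2.25 for the locus of IAPP.

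Among 23 genes of the secretory granule and exocytosis, 13 rose and 7 fell in the authors' deposited table, with a median of 0.11 (list test, adjusted p = 0.0125). The adjusted p was 0.0636 at a correlation of 0.05, and 0.0725, 0.128 and 0.0900 for loci of at least 50 counts, for the rank version and for loci of a single protein-coding gene. SCG3, a granin that sorts granule cargo, rose by 1.55 ± 0.02 to 73869.6 normalized counts, and VAMP8 and SYT5, proteins of vesicle fusion, rose by 0.68 ± 0.06 and 0.61 ± 0.05 in the deposited table. PTPRN, the islet antigen IA-2, rose by 0.15 ± 0.02 in the authors' deposited table. RAB3A (-0.08 ± 0.09) and SYT13 (-0.00 ± 0.02) were among the 3 not past the threshold in the deposited table. Of 14 islet autoantigens of type 1 diabetes, 6 rose and 7 fell in the authors' deposited table, and the list did not pass (adjusted p = 0.656). Its median of -0.11 and the direction of its test were negative, and its mean log2 fold change of 0.10 was positive. GAD1, a glutamate decarboxylase, rose by 1.68 ± 0.20 in the deposited table, with a Cuffdiff q of 0.0564. Of 14 genes disallowed in mature beta cells or tied to their dedifferentiation, SOX9, MYC and HES1 rose and SLC16A1, POU5F1 and LDHA fell in the authors' deposited table. SOX9 rose by 2.40 ± 0.32 and MYC by 1.99 ± 0.36, both under 100 normalized counts, and the lactate transporter gene SLC16A1 fell by 1.63 ± 0.07 in the deposited table. The median of this list was 0.44 and its mean 0.42, while the list test pointed down (adjusted p = 0.606).

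Of 8 markers of other islet endocrine cells, 2 rose and 2 fell in the authors' deposited table, and TTR, the most abundant, stood at -0.18 ± 0.02 with a mean of 33040 normalized counts. Ductal markers rose for 4 of 7 loci in the deposited table, among them KRT19 at 0.27 ± 0.04 and ANXA4 at 0.59 ± 0.04. Of 6 markers of fibroblasts and stellate cells, COL1A1 and ACTA2 rose by 1.39 ± 0.06 and 3.51 ± 0.76 in the authors' deposited table, the second from 1.89 to 21.5 normalized counts. Of 5 acinar markers CPA1 fell by 0.42 ± 0.06, and of 4 endothelial markers ESAM stood at -1.33 ± 0.15 in the deposited table. The leukocyte markers had 0 higher and 2 lower of 8 in the authors' deposited table, and PTPRC, the pan-leukocyte marker CD45, had a mean of 1.69 normalized counts.

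Transcript isoforms were compared in the authors' deposited Cuffdiff isoform table, where 9440 of 95649 tested isoforms passed q under 0.05, 4944 higher and 4496 lower. The 7197 of them with a gene symbol belonged to 5748 genes, and in 59 genes such isoforms moved in opposite directions in the deposited table. Isoforms of the peptide transporter TAP1 rose from 1.36 to 1029 FPKM, of WARS from 2.48 to 369 FPKM, of PSMB10 from 1.43 to 182 FPKM and of IRF1 from 1.86 to 194 FPKM in the authors' deposited table. The largest falls included isoforms of NUMA1, a mitotic spindle protein, from 11.9 to 1.17 FPKM and from 31.2 to 4.90 FPKM in the deposited table, although the gene as a whole stood at 0.30 in the count table. Isoforms of FAM101B and of the cadherin CDH17 fell from 8.87 to 1.15 FPKM and from 9.56 to 1.70 FPKM in the authors' deposited table. These isoforms stood at -2.95 and -2.49 on the log2 scale, and their genes at -2.97 and -1.32 in the count table. Among genes with opposite isoforms, the lipoprotein-binding HDLBP had an isoform that fell from 72.04 to 52.0 FPKM and another that rose from 66.6 to 92.6 FPKM, both with a deposited q of 0.00808. The cyclin-dependent kinase inhibitor CDKN2C had isoforms that went from 161 to 127 FPKM and from 22.7 to 44.2 FPKM in the deposited table, and the transcription factor MAZ isoforms from 37.1 to 18.0 FPKM and from 9.12 to 21.4 FPKM, with no call for the gene in the count table (adjusted p = 0.235). The ribosomal protein RPL9 and the calcium channel subunit CACNA2D1 had isoforms that rose from 5.16 to 18.2 FPKM and from 116 to 151 FPKM, while others fell from 357 to 306 FPKM and from 22.3 to 12.3 FPKM, in the authors' deposited table. Isoform levels are estimates that divide shared reads, and 2243 of the called isoforms were assembled from these reads without a gene symbol of their own.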

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

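All tests in this part were chosen after the results were seen. The comparisons of named genes do not use 675 loci without a gene name, of at least 50 counts and with a named neighbour. Of these, 7 rose by at least 4 on the log2 scale in the authors' deposited table, and they stand here for that reason. Reads from named genes nearby are not excluded for them. Coordinates are those of the bundle of assembled transcripts that holds each locus, not of the locus itself. MSTRG.17033 (chromosome 17, 47715761 to 47718080) had a deposited log2 fold change of 9.81 ± 1.19, a fitted value against a control group listed at 0 FPKM, and was at least 159-fold higher against a floor of 3 reads over that group. MSTRG.2635 (chromosome 1, 155335268 to 155859400) rose by 5.57, and its neighbour MSTO1 stood at 0.72. MSTRG.11880 (chromosome 14, 103266596 to 103274484) rose by 5.33 beside LINC00605 at 2.92, and MSTRG.12668 (chromosome 15, 44711477 to 44718877) by 4.67 in the same bundle as B2M at 4.08, in the deposited table. MSTRG.23032 (chromosome 2, 169645425 to 169776989) rose by 4.18 while its neighbour, the locus of KLHL23 and PHOSPHO2, stood at -0.29 and PTCHD3P2 in the same bundle at 2.38. MSTRG.34817 (chromosome 6, 157239723 to 157272548) and MSTRG.21164 (chromosome 2, 13440903 to 13533382) rose by 4.15 and 4.13 in the authors' deposited table.

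Of the 675 loci, 70 rose and 35 fell at least 2-fold in the authors' deposited table. For 20% of the 70, 14 loci, the neighbouring named locus rose at least 2-fold, against 4.59% among all 675 and at most 15.7% in 10000 shuffles. Transcription from the neighbour may therefore account for part of these loci, such as the one in the bundle of B2M. For 45 of the 70 the neighbour did not pass the threshold or moved less than 1.5-fold. The neighbour was the nearest named locus by identifier, so another gene of the same bundle can have risen, as for MSTRG.23032 and for MSTRG.11719, whose bundle (chromosome 14, 92902283 to 93116320) spans CHGA. For the 45, a response of their own and reads from another transcript cannot be told apart, since the tables give no strand.

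Some loci had many fragments in the FPKM table and few counted reads. INSM1 had a mean of 20.02 normalized counts and 416 FPKM in control in the authors' deposited tables. Of 125 such loci, 50 held a single symbol and a single protein-coding gene, and only these were given a length. Their median exonic length was 2768.5 bases, with the annotated exons of each gene merged. The other loci of at least 10 FPKM chosen in the same way had a longer median of 5433 bases. Merged exons can exceed a single transcript, and loci without a protein-coding gene were left out, so short transcripts were not excluded. Reads left out because they overlap another locus stay open: 80.0% of the 50 loci had an overlapping gene or an undercounted partner, which did not pass Fisher's exact test against 5562 other loci (p = 0.0682). Its parts differed: a partner was found for 30% against 6.08% (Fisher's exact p = 2.11e-07), an overlapping gene for 66% against 65.7%. Loci of a single exon made up 48% against 1.26% (Fisher's exact p = 8.88e-31), for which no explanation was tested, and no biological explanation was tested.

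As deposited, rare loci rose and abundant loci fell more often. The median log2 fold change was 0.19 under 100 counts and -0.06 from 1000 counts in the authors' deposited tables. An offset shared by all loci would give both the same median, and the difference was 0.25 (95% bootstrap interval 0.23 to 0.27, 1000 draws), which argues against it as the whole cause. The share of falls among called abundant loci, 57.9% as deposited, was 49.8% after re-centring on those loci. Re-centring moves this share toward an even split by its construction, so it cannot show whether an offset accounts for that part. A response in which silent genes are switched on, and a depth-related bias, may both remain, and the second was not tested.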

How the results depend on the processing

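Of the alternatives, 3 were chosen after the results were seen, namely re-centring, loci of a single protein-coding gene with undercounted loci left out, and lists without RefSeq synonyms. Among genes of the naming rule and lists past the threshold, none changed direction under an alternative that gave it a value. For genes, that alternative was the Cuffdiff table alone. Genes named for the largest rises and falls had been chosen for the same direction in that table. Their unchanged direction was therefore fixed by the choice and is no check. Of genes and lists not past the threshold, PDX1 went from -0.02 to 0.00583 with Cuffdiff. The dedifferentiation list pointed up in the rank version (adjusted p = 0.508) and down otherwise. With the Cuffdiff table in place of the count table, 7798 genes differed, 3887 higher and 3911 lower, of 21865 tested against 30206. Fewer genes tested accounts for only a small part of the change. Among 20201 loci tested by both tools, 3820 were called in the count table only and 646 in the Cuffdiff table only. A minimum of 2-fold left 2960 loci, 1972 higher and 988 lower, by its construction. In the Cuffdiff gene table it left 2166 genes, 1377 higher and 789 lower, and among isoforms it left 3735, 2388 higher and 1347 lower. Over loci of a single protein-coding gene, 3539 were higher and 4519 lower of 12997 tested, fewer by construction. Under the remaining alternatives the number of loci that differed lay between 9669 at a minimum of 100 counts and 12409 at an adjusted p under 0.1. Re-centring on abundant loci gave 6197 higher and 5142 lower, so the majority turned from lower to higher.

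The number of lists called lay between 13 and 16, against 15. Lists called lower were 2 in the rank version, 2 without shared genes and 2 without RefSeq synonyms, against 1. The added list was beta cell identity in each (adjusted p = 0.00332, 0.0304 and 0.0334, against 0.0824), and its other alternatives ran from 0.0518 to 0.219. The third depended on ERO1B alone, and for the others the cause was not tested. Receptors of the cocktail passed in the rank version (adjusted p = 0.00825). Over all lists and alternatives, 128 results were the same, 8 were weaker and 4 were stronger. Among named genes, 77 were the same and 10 weaker with Cuffdiff, and the cause was not tested.

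No paired analysis was possible because the tables hold 1 comparison and no values per library. For the same reason a replicate block, leaving out each replicate, other splits of the samples, another normalization or count tool, a filter on low counts before the fit, a pseudocount and an estimated correlation between genes were not run. Depth limits the rare loci: under 10 counts the median SE was 1.056, and 409 higher and 79 lower of 10350 loci passed the threshold.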

Other observations

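The families in this part were chosen after their values were seen, as were its tests except that of induced genes lying near other induced genes. They hold only loci of a single protein-coding gene and at least 50 normalized counts, so members that share a locus or are rarer were not counted. Of 70 loci of cytosolic ribosomal proteins, 58 fell and 4 rose in the authors' deposited table, with a median of -0.26, where 57.9% of all called loci of at least 1000 counts were lower, and after re-centring on abundant loci 49 fell and 4 rose. RPL3, RPL4 and RPL6 stood at -0.67, -0.58 and -0.52, and RPS27L, a target of p53, rose by 0.23 in the deposited table. Of 25 RNA polymerase subunit genes counted 17 fell and 2 rose in the authors' deposited table (16 and 3 re-centred), with POLR1E at -0.81 and the RNA polymerase III subunit POLR3D at 1.12. Of 12 genes of the 20S proteasome counted, with PSMA names or PSMB1 to PSMB7, 8 rose in the deposited table, led by PSMA5 (1.11) and PSMA6 (1.06). PSMB5 fell (-0.18), and PSMB6 (0.06), PSMB7 (0.07) and PSMA7 (0.05) were not past the threshold. After re-centring 11 rose and 1 fell. Of 35 genes with NDUF names, most of them of complex I, 15 fell and 4 rose in the authors' deposited table, 9 and 6 re-centred.

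The 5 metallothionein genes counted rose in the authors' deposited table, from MT1X at 1.74 to MT1E at 4.71 and MT2A at 5.59, and 5 rose re-centred. Of 10 PARP genes counted 7 rose, led by PARP14 (6.42), PARP9 (4.22) and PARP3 (3.31), while PARP1 (-0.48), PARP2 (-0.89) and PARP16 (-0.35) fell in the deposited table, and re-centred 7 rose and 3 fell. The Notch receptor genes counted fell, NOTCH3 at -1.93, NOTCH2 at -1.24 and NOTCH1 at -0.92, while the ligands JAG1 and DLL3 rose by 1.62 and 1.06 and the ligand DLL1 stood at -0.34 in the authors' deposited table. HEY1 (-0.97) and HES6 (-0.50) fell as well, so 6 of the 8 genes of this family counted were lower. HES1, which was not among them, rose.

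CCND1, which drives entry into the cell cycle, and its opponent CDKN1A, the cyclin-dependent kinase inhibitor p21, both rose while all members of the cell cycle list fell. CCND1 went from 0.637 to 284 normalized counts and CDKN1A from 176 to 1146 in the authors' deposited table. GC, the vitamin D binding protein gene, rose by 2.13 from 35201 to 154251 normalized counts in the deposited table.

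Induced genes lay near each other in the genome. Of 469 genes that rose at least 4-fold, among 11790 genes, 25.4% had another such gene within 100 kb, against a median of 10.2% and at most 17.9% in 10000 shuffles (permutation p = 0.0001, the smallest they can give). Gene families may account for much of this: among pairs of unlike names the share was 14.3%, against a median of 9.8% and at most 17.1% (permutation p = 0.0156), and among such pairs outside the MHC region (chromosome 6, 28500000 to 33500000) 13.0%, against a median of 9.8% and at most 19.6% (permutation p = 0.0529). Whether unlike induced genes outside the MHC region share neighbourhoods beyond chance stays open.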
